A study of Arabidopsis thaliana with 21 samples.

How the data were processed

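Small RNA libraries of inflorescence tissue were analysed for 2 groups, wild-type Col and spt5l, with 2 libraries each; groups and replicate numbers were taken from the sample titles. Per the labels' protocols, small RNAs of 15 to 30 nt were selected on a gel and libraries were made with a TruSeq small RNA kit. The submitters' processing notes name cutadapt 1.9.1, Bowtie 1.1.0 and the genome build TAIR10, without saying which step each served. The deposited files give, per library, a list of distinct sequence tags and the read count of each, with no header, and the counts are not normalized; this unit was taken from the values, which are whole numbers with different sums per library. The 17 GRO-seq samples of the series were not analysed here.

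The content of the files was checked before testing. No tag among 3488481 distinct tags occurred together with its reverse complement. Of 162 known mature small RNA sequences, 74 had 20 reads or more, of which 39 were found as written, 35 as their reverse complement and 0 in both orientations. Mature sequences encoded at several identical loci were missing. The files therefore look like reads with a single match in the genome, written in the orientation of its forward strand, although no source used here states this step. Small RNAs from repeated sequences, including many siRNAs of repeated elements and the main members of several miRNA families, are then not measured, small RNAs with a base that differs from the reference are probably left out, the strand of a read is not known, and its 5′ end cannot be told from its 3′ end. Total reads per library were 10586467, 7790318, 5103329 and 7850079, of which 94.2%, 94.9%, 95.0% and 93.1% were 18 to 28 nt long. At these depths 3 reads correspond to 0.301, 0.406, 0.619 and 0.41 CPM in Col replicates 1 and 2 and spt5l replicates 1 and 2.

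The design fixed before the data were examined counted 24-nt siRNAs in genome windows, at genes and by genomic class, and 21- and 22-nt reads at genes. No genome sequence was used here, so these tests were not run, nor were the fixed lists of phased-siRNA genes and of genes with methylation-controlled promoters. The shares of reads from rRNA, tRNA and organelles and the reads at SPT5L itself were not counted either. The mutant label was not checked. The planned replacement, a test of each 24-nt tag, was used. miRNA and ta-siRNA families were counted from mature sequences written down from general knowledge after the files had been opened and before any test. A tag of 20 to 22 nt counted for a family when it held bases 2 to 19 of a mature sequence in either orientation; 507 tags fell in 82 families. These families and all other tags of 20 to 22 nt were tested together, 11535 features of 841136. In addition, and chosen after the data were examined, 24-nt tags were joined into 527323 overlap groups wherever the last 20 to 23 bases of 1 tag equalled the first bases of another and this overlap occurred in 1 pair of tags only.

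Tests used edgeR 4.0.16 (quasi-likelihood, default abundance filter, spt5l against Col, no covariate) in R 4.3.3. The library size was the number of reads of 18 to 28 nt with a normalization factor of 1, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Standard errors were taken as the log2 fold change divided by the square root of the test's F. Family lists fixed beforehand were also adjusted over the list alone and tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated one. Shares of size classes and terminal bases were compared by exact permutation tests in scipy 1.17.1. A group or tag was called nearly absent from a genotype when it reached 10 CPM in both libraries of the other genotype and lay below 5% of each of them in both of its own. Named features followed a rule fixed beforehand: among features with an adjusted p below 0.05, both spt5l libraries on 1 side of both Col libraries and a mean abundance at or above the median, those with the largest rise and the largest fall; for families, up to 6 in each direction that passed; and for each list the called members and otherwise up to 4 with the highest mean. As tags carry no gene name, the number of named 24-nt tags was reduced to 2 in each direction, and single tags of 21 and 22 nt, after their values had been seen, were not named.

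Alternatives were TMM factors, DESeq2 1.42.0 with its own size factors, miRNA reads as library size, no abundance filter, a 2-fold limit, thinning to the shallowest library, leaving out each library, a replicate block, 21-nt tags alone and distinct tags in place of reads. Chosen after the data were examined were offsets by GC content (smoothed median log ratio of each library per GC class), exact mature sequences, limits of GC content and other limits for near absence. In simulated counts for 56543 24-nt tags with 200 changed tags, edgeR recovered 45% of 16-fold and 0% of 4-fold changes with 1 false call; for 39485 overlap groups it recovered 73% and 9% with 4 false calls, and for 11535 features of 20 to 22 nt 2% and 0% with 0 false calls. With a GC trend added to the simulated groups, false calls were 93 without and 3 with the offsets. The added trend was weaker than that of the data at high GC content. The 3 false calls therefore do not show how well the offsets work there. With that trend and no offsets, recovery of 16-fold changes was 44% for 24-nt tags, 69% for groups and 20% for features of 20 to 22 nt. With the offsets it was 51%, 67% and 18%. Overlap grouping of 2000 simulated loci joined tags of different loci in 0 groups and split a locus into 3.1 groups on average, so a site can count as several groups. The tags of each group were also placed on 1 line by their overlaps, chosen after the data were examined, to give the share of Col reads over the best covered base; all tags of 500 of 500 simulated loci were put in their place.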

Results

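The series combined GRO-seq, which records nascent transcripts, with small RNA sequencing in inflorescences of Arabidopsis thaliana. The 4 small RNA libraries were analysed here, and the 17 GRO-seq samples were not analysed here. The small RNA libraries came from wild-type Col-0 plants (Col, 2 libraries) and from the spt5l-1 mutant (spt5l, 2 libraries). SPT5L, also called KTF1 (AT5G04290), is an SPT5-like protein that associates with RNA polymerase V, a polymerase that acts in RNA-directed DNA methylation. Each file listed distinct sequence tags with their read counts. The libraries held 10586467 and 7790318 reads in Col replicates 1 and 2, and 5103329 and 7850079 reads in spt5l replicates 1 and 2. Of these, 9968882, 7396219, 4846534 and 7309497 reads were 18 to 28 nt long, and abundances are given in CPM, with those reads as the library size. The labels do not say whether the libraries of a genotype came from separately grown plants, so p-values measure the spread between these libraries, which may be technical. Reads are not independent molecules, so intervals and floors cover counting error only.

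The comparison of spt5l with Col sets the small RNAs of plants without SPT5L beside those of the wild type. The 24-nt class was the most abundant length in every library. It made up 59.5% and 56.0% of the 18- to 28-nt reads in the Col libraries and 63.5% and 51.7% in the spt5l libraries. The mean was 57.7% ± 2.47 (SD, n = 2) in Col and 57.6% ± 8.36 (SD, n = 2) in spt5l, and the difference was smaller than the spread between replicates (exact permutation test, two-sided, p = 1). The 21-nt class, which holds most miRNAs, made up 7.98% ± 1.65 (SD, n = 2) in Col and 9.16% ± 3.15 (SD, n = 2) in spt5l (exact permutation p = 0.667). The 22-nt class made up 8.61% ± 0.844 and 7.41% ± 3.36 (SD, n = 2 each; exact permutation p = 1). With 2 libraries against 2, the smallest p this two-sided test can give is 0.333. spt5l replicate 1 held fewer distinct sequences than the other libraries. After thinning to 3077292 24-nt reads, it had 212765 distinct 24-nt tags, against 419020 and 400594 in the Col libraries and 411248 in spt5l replicate 2.

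**Figure D1:**
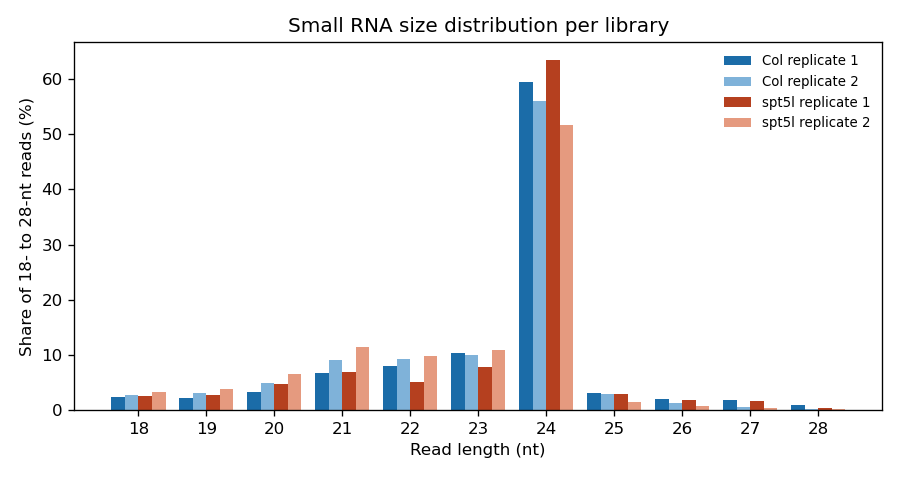
Share of 18- to 28-nt reads (%) at each read length in the 4 libraries; each bar is 1 library. The 24-nt class leads in every library, between 51.7% and 63.5%, and the spt5l libraries lie on either side of the Col libraries.

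A subset of 24-nt siRNA groups had almost no reads in spt5l. To follow groups rather than single sequences, 24-nt tags were joined into groups where their ends overlapped exactly, a step chosen after the data were examined. In Col, 5744 groups reached 10 CPM in both libraries. Of these, 490 groups (8.53%) were below 5% of both Col libraries in both spt5l libraries. In the other direction, none of the 4966 groups that reached 10 CPM in both spt5l libraries was below 5% in both Col libraries. The nearly absent groups together held 376736 24-nt reads in Col and 2333 in spt5l, or a mean of 21568 CPM against 189 CPM. All 490 were among the groups called lower by edgeR's quasi-likelihood test at an adjusted p below 0.05, which is no separate evidence, as they were selected from the same counts. For 175 of them no read was found in either spt5l library. Between single libraries, 744 to 852 groups present in a Col library were below 5% of it in an spt5l library, and 0 to 38 groups the other way, with the 38 of 6782 present in spt5l replicate 1 and below the limit in Col replicate 2. Between the 2 libraries of 1 genotype the count was 1 to 5. The 21- and 22-nt reads from the nearly absent groups summed to a mean of 3758 CPM in Col and 168 CPM in spt5l, a difference that was not tested. Nearly absent groups between 30% and 45% GC gave only 320 and 350 CPM of these in the Col libraries and 5.36 and 11.4 CPM in the spt5l libraries. Most of the sum thus came from groups outside that GC range. Near absence varied with how a group's reads lay. It was found in 449 of the 3853 groups with 99% or more of their Col reads over 1 base and in 19 of the 1288 groups (1.48%) with 5% or more of them off every base. Groups were joined from the tags of every library, so tags seen only in spt5l could widen the groups kept there, and part of this difference may come from the grouping. Tags that differ from a deep tag by 1 base were rare in the files, found for 16 of the 300 deepest 24-nt tags, so small RNAs with a changed base may be missing from them.

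The nearly absent groups occurred in each range of GC content counted, and their share was largest at 60% GC or more. They made up 9.84% of the 61 Col groups below 30% GC, 6.16% of the 3247 groups between 30% and 45% GC, 8.49% of the 1367 groups from 45% to 50%, 131 of the 1008 groups from 50% to 60%, and 60.7% of the 61 groups at 60% or more. The 3047 other groups between 30% and 45% GC summed to 207323 and 193732 CPM in the Col libraries and to 299384 and 233325 CPM in the spt5l libraries, whereas the 200 nearly absent groups of the same range summed to 8286 and 6822 CPM in Col and to 37.8 and 51.03 CPM in spt5l.

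**Figure D2:**
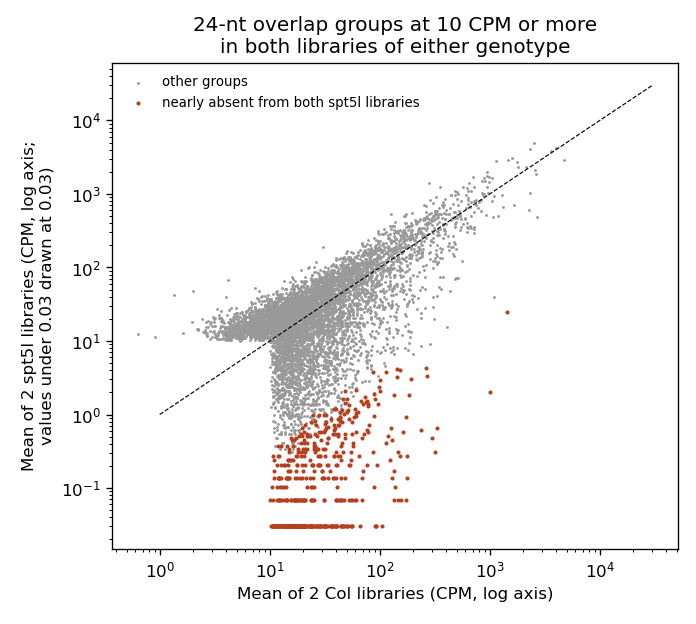
Each point is an overlap group of 24-nt tags with at least 10 CPM in both libraries of either genotype; the axes give its mean CPM over the 2 Col and the 2 spt5l libraries on log scales, and the dashed line marks equal values. The 490 groups in red lie below 5% of Col in both spt5l libraries, and no group lies in the matching place above the line.

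Tested one by one, more 24-nt tags were called lower than higher in spt5l, although the median tag was slightly higher. Of 1009850 distinct 24-nt tags, 56543 had enough reads to be tested, and at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg) 6689 were lower and 1446 higher. The median log2 fold change of all tested tags was 0.15, and TMM factors moved it to -0.11. Between 30% and 45% GC the median was 0.71, and 1464 tags were called lower and 1132 higher, while 2128 and 4942 had an unadjusted p below 0.05. The counts of all tags moved with the library size used, to 3804 lower and 269 higher when miRNA reads set it, and with the libraries kept. They were 3490 and 1161 without Col replicate 1, 3399 and 377 without Col replicate 2, 6621 and 706 without spt5l replicate 1, and 7654 and 5410 without spt5l replicate 2. Among the overlap groups, 5445 were lower and 1220 higher of 39485 tested, 2800 and 770 without Col replicate 1, 2907 and 336 without Col replicate 2, and 7508 and 5192 without spt5l replicate 2. The tags named below had the largest changes among those that passed the test, with no overlap between genotypes. The tag ACCGACCGTCAGACATGGATGAGA had 967 and 760 reads in Col and none in spt5l, a fall of at least 194-fold against a floor of 3 reads per library (adjusted p = 0.00024, edgeR). The tag AGTGATCACCGGTTTTCTAGGAAT had 992 and 494 reads in Col and none in spt5l, at least 162-fold lower (adjusted p = 0.000334, edgeR). In the other direction, the tag CTGACCCTGGAAAGCTTTAGAACT rose from 5 and 0 reads to 156 and 157 reads, with a log2 fold change of 6.51 ± 0.87 (SE; adjusted p = 0.00135, edgeR). Scaled by library size its pooled ratio was 89.4, with a 95% counting interval of 37.9 to 277, and without Col replicate 2 its log2 fold change was 5.69, while without Col replicate 1 no Col read was left. The tag GAGTAGAGATTCCAAAGGATGAAC rose from 1 and 2 reads in Col to 102 and 51 in spt5l, a ratio of 72.9 after scaling by library size with a 95% counting interval of 24.5 to 357 (adjusted p = 0.00258, edgeR). Its log2 fold change was 6.18, and it was 5.59 without Col replicate 1, 6.89 without Col replicate 2, 5.19 without spt5l replicate 1 and 6.77 without spt5l replicate 2. No genome sequence was used here, so the tags carry no position or gene name.

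The base composition of the libraries differed between the genotypes at every small RNA length. The 24-nt reads were 45.4% ± 0.617 GC in Col and 41.4% ± 0.62 GC in spt5l, and the 21-nt reads 50.0% ± 0.0787 and 43.4% ± 0.7 (SD, n = 2 each). Over distinct tags the differences were smaller, -1.43 points at 24 nt and -2.40 points at 21 nt. The 2 libraries of a genotype lay on the same side in both cases. Reads with 60% GC or more made up 6.17% and 7.28% of the 18- to 28-nt reads in Col and 0.421% and 0.548% in spt5l. The median log2 fold change of the tested 24-nt tags was 0.84 at 30% to 35% GC, 0.14 at 45% to 50%, -1.22 at 50% to 55% and -5.12 at 60% to 65%. The 21- and 22-nt tags followed, with medians of 1.34, 0.59, -0.53 and -3.72 in the same bins. When each library was given an offset by GC content, chosen after the data were examined, 2950 24-nt tags were lower and 395 higher, and 3432 overlap groups were lower and 907 higher. Of the 5445 groups lower without the offsets, 3270 were also lower with them. These included 489 of the 490 nearly absent groups, which were selected from the same counts for a large fall, and all 453 of those under 60% GC. The offsets did not level the trend at 60% GC or more, where the median log2 fold change was still -2.93 for 24-nt tags, -2.40 for groups and -1.43 for 21- and 22-nt tags with them.

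**Figure D3:**
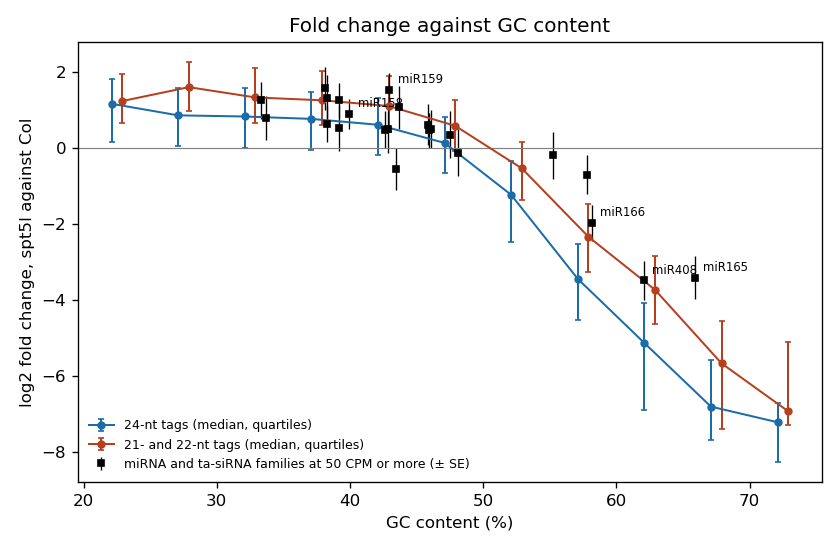
log2 fold change of spt5l against Col as a function of GC content (%). Circles with bars are medians and quartiles of the tested 24-nt tags (blue) and 21- and 22-nt tags (red) in bins of 5 points, and black squares with SE bars are families of known miRNAs and ta-siRNAs with a mean of 50 CPM or more; the medians fall from above 0 below 45% GC to -5.12 and -3.72 at 60% to 65% GC, and miR408 and miR165 lie at 62.1% and 65.9% GC.

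Of 61 families of known miRNAs and ta-siRNAs with enough reads, 2 passed the test over all features of 20 to 22 nt, and both fell in spt5l. miR408, which acts on transcripts of copper proteins, fell from 2877 ± 255 CPM in Col to 259 ± 42.4 CPM in spt5l (SD, n = 2 each), with a log2 fold change of -3.47 ± 0.50 (SE; adjusted p = 0.0266, edgeR). miR165, which with miR166 acts on class III HD-ZIP transcription factors, fell from 1228 ± 111 to 116 ± 49.6 CPM, with a log2 fold change of -3.40 ± 0.57 (SE; adjusted p = 0.0296, edgeR). The mature miR165 sequence itself had 0 reads in the 4 libraries, so its values rest on length variants and the opposite strand of the hairpin, and with exact sequences its log2 fold change was -1.31 (adjusted p = 0.295). Both have a high GC content, 62.1% and 65.9%, in the range that the offsets did not level. With the offsets for GC content neither passed the test, at log2 fold changes of -0.67 ± 0.22 (adjusted p = 0.358) and 0.27 ± 0.30 (adjusted p = 0.77), the latter with the opposite sign. No family passed in the upward direction with edgeR, 10 did at an unadjusted p below 0.05, DESeq2 called 2 higher and 7 lower, and edgeR with TMM factors 1 higher and 7 lower. Without spt5l replicate 1 the counts were 3 lower and 4 higher, and without spt5l replicate 2 they were 5 and 3. With the GC offsets edgeR called 0 families in either direction, while 3 were lower and 2 higher at an unadjusted p below 0.05. Summed over families, miRNAs reached 52479 and 70289 CPM in Col and 48038 and 70235 CPM in spt5l, so the totals overlapped. The median log2 fold change of all tested 21- and 22-nt tags was 0.43, and TMM factors moved it to -0.10; the fold changes of families are to be read against that shift.

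Among the 15 measured conserved miRNA families, miR165 was the 1 member that passed over all features, and 2 fell and 1 rose when p-values were adjusted over the list alone. miR166 fell from 27959 ± 7647 to 7190 ± 3853 CPM (log2 fold change -1.96 ± 0.48, adjusted p = 0.0139 over the list alone and 0.0659 over all, edgeR), and its GC content was 58.2%. With the GC offsets its log2 fold change was -0.10 (adjusted p = 0.879), and with exact sequences, among which the mature form had 0 reads, it was -1.16. It passed over all features in 6 of 14 alternatives, among them edgeR with TMM factors (adjusted p = 0.000178), DESeq2 and miRNA reads as library size. The others were the replicate block and the fits that left 1 spt5l library, where the spread comes from the Col pair alone. Without 1 library its log2 fold change ranged from -2.65, without spt5l replicate 2, to -1.50, without spt5l replicate 1. miR159, which acts on GAMYB-like transcription factors, rose from 4158 ± 13.6 to 12147 ± 3304 CPM (log2 fold change 1.55 ± 0.42, adjusted p = 0.0197 over the list alone and 0.0767 over all), and the GC offsets brought it to 0.59 (adjusted p = 0.347). It passed over all features in 5 alternatives, of which all but TMM factors used the replicate block or left 1 spt5l library. miR396 had 1074 ± 14.4 CPM in Col and 2580 ± 509 CPM in spt5l (adjusted p = 0.145 over all), and miR319 had 2750 ± 606 and 1703 ± 852 CPM (adjusted p = 0.435). The exact miR319a sequence had 0 reads. Exact miR319c had 530 and 986 of the family's 23141 and 23506 reads in Col, and 384 and 1476 of 5333 and 16854 in spt5l. The miR319 values thus rest mostly on other tags, and with exact sequences its log2 fold change was 0.59, against -0.69. The camera test of the list gave an adjusted p of 0.716 with the preset correlation and an adjusted p of 0.891 with an estimated correlation. Among the 7 nutrient-responsive families, miR408 fell over all features, and over the list alone miR827, a phosphate-starvation miRNA, also rose, from 2.61 and 4.73 CPM to 20.4 and 17.0 CPM (log2 fold change 2.35 ± 0.72, adjusted p = 0.0274 over the list alone and 0.0957 over all). Its GC content was 33.6%, and with the GC offsets its log2 fold change was 0.88 (adjusted p = 0.568). miR397, which acts on laccases, had 1377 ± 450 and 947 ± 534 CPM (log2 fold change -0.54, adjusted p = 0.593 over all, edgeR). Its log2 fold change was -0.06 without spt5l replicate 1, -1.27 without spt5l replicate 2 and -1.54 with the GC offsets (adjusted p = 0.193). miR399 had 14.8 ± 9.61 and 3.56 ± 3.87 CPM, with a log2 fold change of -2.02 (adjusted p = 0.231, edgeR). Its log2 fold change was -1.13 without Col replicate 1 and -4.14 without spt5l replicate 2, and DESeq2 called it lower (adjusted p = 0.0106). The camera test of this list gave adjusted p = 0.459, and adjusted p = 0.891 with an estimated correlation.

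None of the 24 measured young, Brassicaceae-specific miRNA families passed the edgeR test in the main setting, over all features or over the list alone. The most abundant, miR158, had 12823 ± 2648 CPM in Col and 23998 ± 2931 CPM in spt5l (adjusted p = 0.198). Its log2 fold change was 0.90, and it was 1.02 without spt5l replicate 1 and 0.77 without spt5l replicate 2. It passed over all features as higher with the replicate number as a block (adjusted p = 0.000109, edgeR). These numbers share only a label, so the block has no known basis in the design. miR780 had 1651 ± 121 and 2556 ± 894 CPM, miR161 had 1720 ± 38.0 and 2444 ± 1165 CPM, and miR824 had 554 ± 364 and 712 ± 380 CPM. Of the 24 log2 fold changes 20 were above 0, with a median of 0.86, which the GC offsets brought to -0.01. The camera test gave adjusted p = 0.159, and adjusted p = 0.891 with an estimated correlation. The 5 measured families that act on the silencing machinery did not pass either. The exact mature sequences of miR162, miR168 and miR390 had 0 reads in the 4 libraries. The values of these families rest on variant tags or on the opposite strand of the hairpin, so the acting strands themselves were not measured. miR403, which acts on ARGONAUTE2, had 1051 ± 114 CPM in Col and 1479 ± 453 CPM in spt5l, and miR168, which acts on ARGONAUTE1, had 175 ± 80.7 and 154 ± 80.1 CPM. miR162 had 7.38 ± 1.22 and 7.68 ± 2.69 CPM, and miR173, the trigger of TAS1 and TAS2 siRNAs, had 7.36 ± 2.60 and 6.75 ± 3.42 CPM. The camera test of these families gave adjusted p = 0.716, and adjusted p = 0.891 with an estimated correlation. The pollen-associated miR845, included as a marker of another cell type, had 47.9 ± 30.6 CPM in Col and 47.2 ± 21.5 CPM in spt5l (adjusted p = 0.992).

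The 4 measured ta-siRNAs were all higher in both spt5l libraries than in both Col libraries, and 3 passed the test adjusted over the list alone but none over all features in the main setting. The TAS1 siRNA siR480 had 981 ± 383 CPM in Col and 2345 ± 510 CPM in spt5l (log2 fold change 1.26 ± 0.50, adjusted p = 0.17 over all). The TAS2 siRNA siR1511 had 70.1 ± 25.5 and 209 ± 11.3 CPM (1.57 ± 0.58, adjusted p = 0.148), and the TAS1 siRNA siR255 had 2.29 ± 0.398 and 8.37 ± 0.162 CPM (1.87 ± 0.76, adjusted p = 0.178). Adjusted over the list alone, these 3 had an adjusted p of 0.0417. The exact siR255 sequence had 0 reads in the 4 libraries. Its values rest on other tags that hold bases 2 to 19, with 20 and 19 reads in Col and 40 and 62 in spt5l. Over all features, siR480 and siR1511 passed with the replicate number as a block (adjusted p = 0.00228 and 0.0306, edgeR). These numbers share only a label, so the block has no known basis in the design. The TAS3 siRNA tasiR-ARF, which acts on auxin response factors, had 59.6 ± 7.92 and 125 ± 25.5 CPM (1.07 ± 0.57, adjusted p = 0.0882 over the list alone). Their GC content lay between 33.3% and 43.7%, and with the GC offsets none passed, at log2 fold changes of -0.24 ± 0.26 for siR480, 0.32 for siR1511, 0.65 for siR255 and 0.14 for tasiR-ARF. The camera test of the list gave adjusted p = 0.159, and adjusted p = 0.891 with an estimated correlation.

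Outside the known families, 121 of 10084 tested tags of 21 and 22 nt fell in spt5l and 4 rose (edgeR, adjusted p below 0.05), whereas 1138 and 1107 had an unadjusted p below 0.05. Of the 121, 99 had a GC content of 60% or more and 18 a GC content from 50% to 60%. DESeq2 called 908 lower and 118 higher, and edgeR with GC offsets called 1 lower and 0 higher. Without spt5l replicate 2 the counts were 746 and 399, without spt5l replicate 1 they were 296 and 139, without Col replicate 1 186 and 7, and without Col replicate 2 195 and 9.

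The 24-nt reads of both genotypes often started with A or ended with T, where a 5′ A, the base that AGO4 prefers, would show. Because tags were written in 1 orientation of the genome, the terminal A share is the mean of the share of reads that start with A and the share that end with T. This share mixes a 5′ A with a 3′ U, which cannot be told apart here, so it is not the share of 5′ A. It was 45.9% and 43.8% in the Col libraries and 50.3% and 49.8% in the spt5l libraries, above the 26.7%, 26.4%, 28.4% and 28.3% found at the middle bases of the same reads. The mean was 44.8% ± 1.52 in Col and 50.0% ± 0.304 in spt5l (SD, n = 2 each), and both spt5l libraries lay above both Col libraries (exact permutation test, two-sided, p = 0.333, the smallest this design can give). Among 24-nt reads of 40% to 50% GC the libraries overlapped, at 47.6% and 46.2% in Col and 46.8% and 47.5% in spt5l. Both spt5l libraries stayed above both Col libraries at 30% to 40% GC, at 57.5% and 57.9% against 56.8% and 55.0%, and below 30% GC, at 65.6% and 65.7% against 65.1% and 63.7%. They overlapped at 50% to 60% GC, at 35.7% and 37.1% against 36.1% and 35.3%, and lay below both Col libraries at 60% GC or more, at 23.2% and 24.3% against 25.8% and 25.7%.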

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

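Of the settings below, the offsets for GC content, the range of 30% to 45% GC, exact mature sequences, every setting for overlap groups and, for 24-nt tags, all but TMM factors were chosen after the data were examined. For 24-nt tags, the 6689 lower calls became 3804 with miRNA reads as library size, 2950 with GC offsets, and 1464 when only tags of 30% to 45% GC were counted, which is a smaller set by construction. Leaving out 1 library gave 3399 to 7654. The 1446 higher calls became 882 with TMM factors, 963 with DESeq2, 269 with miRNA reads, 739 without a filter, 734 after thinning and 395 with GC offsets, and 377 to 5410 when 1 library was left out. For overlap groups, the 5445 lower calls became 3432 with GC offsets and 1929 at 30% to 45% GC, with 2800 to 7508 when 1 library was left out; the 1220 higher calls became 432 with miRNA reads and 772 after thinning, with 336 to 5192 when 1 library was left out. More calls were lower than higher in every one of these settings. The share of nearly absent groups, 8.53%, stayed between 5.73% and 12.2% over the scalings, limits, thinning and left-out libraries run. By GC content, however, it ran from 5.52% at 35% to 40% GC to 60.7% at 60% or more. For single tags of 30% to 45% GC it was 4.87%. The 4 named 24-nt tags kept their direction in all 48 combinations of tag and setting. They were picked from the same counts for the largest changes, so this is no separate evidence. Leaving out 1 library moved the difference in the 24-nt share from -0.16 points to between -6.07 and 5.75. Recovery of 4-fold changes was measured in simulated data with the same depth and number of libraries. Without a GC trend it was 0% for 24-nt tags, 9% for overlap groups and 0% for features of 20 to 22 nt. With a GC trend and no offsets it was 9%, 21% and 0%, and with the offsets 2%, 7% and 0%. Each simulation held 100 changes of 4-fold and 100 of 16-fold, far fewer than the calls made for 24-nt tags and groups. The adjusted p depends on how many features change, so these shares need not hold in the data. The simulated spread may also differ from that of single libraries. Whether depth, spread or number of libraries limits recovery was not tested.

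For miRNA families, the 2 lower calls became 7 with TMM factors, 7 with DESeq2, 0 without a filter, 0 after thinning, 0 with GC offsets, 1 with exact sequences and 1 with 21-nt tags, and 2 to 5 when 1 library was left out; the 0 higher calls became 1 with TMM factors and 2 with DESeq2, and 0 to 4 when 1 library was left out. miR408 passed in 10 and miR165 in 8 of 14 alternatives. Of the named families that did not pass in the main setting, miR166 passed as lower in 6, miR159 as higher in 5, miR158 as higher in 3, miR396, miR827 and siR480 as higher in 2 each, siR1511 as higher in 1, and miR399 as lower in 2. miR319 passed as lower with edgeR and TMM factors and with DESeq2 (adjusted p = 0.0112 and 0.027), and miR397 as lower with edgeR and TMM factors (adjusted p = 0.037). The counts of settings passed include the replicate block, whose numbers share only a label. They also include fits that left 1 library of a genotype, where the spread comes from 1 pair of libraries. For 21- and 22-nt tags, the 121 lower calls became 843 with TMM factors, 908 with DESeq2, 73 with miRNA reads, 190 without a filter, 0 after thinning and 1 with GC offsets, and 186 to 746 when 1 library was left out; the 4 higher calls became 66, 118, 5, 7, 0 and 0, and 7 to 399. The rise of the terminal A share of 24-nt reads, 5.19 points, became 3.22 over distinct tags, and 1.83, 0.224 and 0.692 among reads of 30% to 40%, 40% to 50% and 50% to 60% GC.

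Log2 fold changes of 12 of the 22 named families changed sign in at least 1 setting. With GC offsets this gave 0.27 for miR165, 1.17 for miR319, -0.0053 for miR158, -0.64 for miR780, -0.015 for miR161, -0.13 for miR824, -0.47 for miR403, 0.75 for miR168 and -0.24 for siR480. TMM factors gave -0.0309 for miR161, -0.13 for miR824 and -0.435 for miR162, and DESeq2 -0.0296, -0.13 and -0.43. Exact sequences gave 0.59 for miR319, 0.41 for miR168 and 0.11 for miR845, 21-nt tags 0.42 for miR168, and miRNA reads as library size 0.0628 for miR845. With 1 library left out the values ran from -0.0864 to 0.93 for miR161, -0.32 to 1.26 for miR824, -0.84 to 0.38 for miR168, -0.35 to 0.38 for miR162, -0.76 to 0.32 for miR173 and -0.58 to 0.85 for miR845. The cause was not tested for changes other than those under GC offsets.

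The replicate numbers share only a label: deviations of same-numbered libraries correlated at 0.055 over 24-nt tags, 0.036 over groups and 0.057 over features of 20 to 22 nt. With the replicate number as a block, 2717 24-nt tags and 2144 groups were higher, 4 families were lower and 7 higher, 517 tags of 21 and 22 nt were lower and 192 higher, and miR845 had a log2 fold change of 0.0618. The block with GC offsets gave 3412 tags lower and 935 higher, 3452 groups lower, 1 family lower and 2 higher, 72 tags of 21 and 22 nt lower and 20 higher, and log2 fold changes of 0.23 for miR165, 1.17 for miR319, -0.0138 for miR158, -0.64 for miR780, -0.0145 for miR161, -0.0078 for miR824, -0.47 for miR403, 0.86 for miR168 and -0.21 for siR480. The families that passed there were miR319 and miR159, as higher (adjusted p = 6.03e-05 and 0.00877), and miR397, as lower (log2 fold change -1.55, adjusted p = 7.28e-06), so miR319 was called in opposite directions by different settings. Not run without a genome sequence were the planned settings on multiple matches, window sizes, tags of 23 nt, gene bodies alone, pericentromere limits and structural RNA; counting all reads of 18 to 28 nt as library size is the main setting here.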

Other observations

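The tests below on GC content, on few starting molecules, on the number of distinct tags, on groups under 25 tags, on groups narrow and wide, on 21- and 22-nt reads at the same sites, on GC content of distinct tags, the comparison of nearly absent with other groups, and the count of known families, were chosen after the results were seen. Those on groups of 25 tags or more, on reads off every base, on remaining reads and on 21-nt tags elsewhere were set before their values were computed, but the one on groups of 25 tags or more was divided from the rest after its value had been seen. Between 30% and 45% GC, the 200 groups of 24-nt tags that were nearly absent from spt5l were compared with the 3047 other groups in Col. They gave 4.44 reads of 21 and 22 nt per 100 reads of 24 nt, against 12.7 in the other groups. Over all GC contents this order turned, at 17.4 in the nearly absent and 15.9 in the other groups, while the medians of single groups were 3.58 and 8.02. In the 200 groups the terminal A share was 56.8% and 53.8% in the Col libraries, against 49.5% and 47.3%. Counted over all 4 libraries, a group held a median of 10 tags, against 17, at a median of 24.6 and 26.6 CPM in Col. Groups nearly absent from spt5l have few spt5l tags by definition, so their lower tag number is not a trait seen in Col. The groups called higher in spt5l summed to 36850 and 33370 CPM of 24-nt reads in Col and to 99444 and 74814 CPM in spt5l, and their 21- and 22-nt reads to 4997 and 5759 CPM in Col and 8662 and 15180 CPM in spt5l.

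The first pattern is the near absence of 490 groups from both spt5l libraries, for which a library-wide GC trend is argued against as the whole cause, since between 30% and 45% GC, where the median fold change was above 0, 200 groups were nearly absent from spt5l and 0 from Col. Few starting molecules in spt5l replicate 1 are argued against too, since 80.3% of the groups under the limit in replicate 1 were also under it in replicate 2, against 10.3% of all groups present in Col. Base variants in the mutant plants may account for some of it, if such reads are missing from these files, but the layout of the groups cannot decide this. Groups were joined from the tags of every library, so tags seen only in spt5l can add to and widen the groups kept there. Groups with nearly all Col reads over 1 base were nearly absent 7.90 times as often as wider ones. Of the groups under 25 tags, 473 of 4402 were nearly absent, against 17 of 1342 larger ones. The bound set beforehand for those 17 was wrong, because near absence is set on summed reads, and 7 of the 490 groups had 20% or more of their Col reads off every base, of which 6 had 10 or more reads due from there in each spt5l library, and none had that share off every pair of bases, so for these 6 and the other 484 variants cannot be told apart from a loss of siRNAs, nor can a deletion or foreign segment, with 3 or more reads left in each spt5l library in 14.3% of the groups. In the nearly absent groups of 30% to 45% GC, 21- and 22-nt reads lay at 1.67% and 3.55% of the lower Col library in spt5l. The loss was thus not limited to 24-nt reads. These shorter reads were counted by a stretch shared with a 24-nt tag and may be shortened forms of it, so they cannot decide whether only 24-nt siRNAs were lost. Small RNAs elsewhere leave a general loss open, with 2 such 21-nt tags in Col at that GC content and 0 of 29 known families nearly absent. That count of 0 allows a share of up to 10.3% against the 8.53% of the groups. A need of these siRNAs for SPT5L stays open and untested.

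The second pattern is the lower level of GC-rich small RNAs in spt5l. Loss of 24-nt siRNAs from GC-rich places alone would shift 24-nt reads most, but the shift was smaller at 24 nt (-4.01 points of GC) than at 21 nt (-6.58 points). This contrast of 2.57 points had an SD of 0.385 with the lengths paired within libraries and 0.794 with libraries taken apart. Over distinct tags the shifts were -1.43 and -2.40 points. Their contrast of 0.976 points had an SD of 0.264 paired within libraries and 0.862 with libraries taken apart. The argument against such a loss rests on these contrasts, with 2 libraries per genotype, and on the presence of a shift at 21 nt. The 21-nt shift is consistent with a GC bias of whole libraries, such as PCR can give, and the shift was -6.79 points at 25 to 28 nt, -13.4 points at 29 to 50 nt and -0.899 points at 51 nt. miR408 lay at percentile 50.4 and miR165 at percentile 83.3 among tags within 2.5 points of their GC content, so their fall may be part of that trend, while the labels give no preparation batch for each library and a genotype effect on all GC-rich small RNAs stays open.

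The third pattern is the low number of distinct tags in spt5l replicate 1. At equal reads it had 0.446, 0.441, 0.419 and 0.519 times the mean of the other libraries at 21, 22, 23 and 24 nt, which is consistent with few starting molecules or heavy PCR copying. The genotype as the cause is argued against by spt5l replicate 2, which had 1.03 times the distinct 24-nt tags of the lower Col library.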
